A study of Petunia axillaris and Petunia integrifolia subsp. inflata and Petunia x hybrida with 42 samples.

How the data were processed

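Arrays of 2 custom Petunia platforms were hybridized with antisense RNA carrying a far-red Alexa Fluor dye, made from total RNA, per the labels' protocols. The growth protocol in the labels names P. axillaris plants for every sample, whereas the organism labels name P. axillaris, P. integrifolia subsp. inflata or P. x hybrida, and the organism and title labels were followed here. Samples were grouped by line or tissue and platform from their titles. The deposited scanner tables give, per probe, the mean and the median of its replicate spots' foreground intensity, on a linear scale with no background subtraction, per the file headers. Most probes had 3 spots. The authors also deposited tables of processed intensity per platform, whose scale, normalization and tool are not given in the sources used here. Set against the scanner values, they were linear, with medians of 766.8 (axillaris array) and 749.4 (inflata array) in the tissue columns and 515.4 and 585.8 in the seed columns.

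In 13 of the 42 columns of the authors' processed intensity tables, values were displaced by 1 line against their probe names. These were 7 columns of P. axillaris tissues and all 6 columns of seeds on the inflata array. As deposited, they correlated with the same array's scanner values at a Spearman rho of 0.0436 to 0.130 across probes. After a shift of 1 line, rho was 0.974 to 0.998. The other 29 columns stood in place, at 0.972 to 0.999. The processed values were used only as an alternative, after this shift.

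The main values were the mean intensities. Background was corrected with limma's nec, a normexp model fitted to the 77 (axillaris array) or 76 (inflata array) negative-control probes with an offset of 50. Values were then put on the log2 scale and quantile normalized between the arrays of a fit. The 154 and 143 control probes were left out after background correction. The 6 seed arrays of a platform and the 15 tissue arrays of a species were normalized and fitted separately. Differences were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over all features of a comparison. Seed calls needed an adjusted p under 0.05, and tissue calls also a fitted difference of at least 2-fold. Counts at 2-fold or 4-fold rest on the fitted difference, unlike the bounds described below for named features. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

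A probe was taken as well above background on an array when its mean intensity exceeded the 95th percentile of that array's negative controls, and as saturated at an intensity of 65535. Where any array of the dimmer group was not well above background, the ratio is a bound, written as at least N-fold. It sets the brighter group's mean against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background, all normalized.

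The files carry probe names and sequences of 35 to 40 nt, and no gene names, and no genome or annotation was used here. The 27 gene lists fixed beforehand, such as anthocyanin and vacuolar pH regulators, matched 0 features, so the tests planned on them could not be run and AN11 itself could not be looked up. Of probes, 2394 on the axillaris array and 2769 on the inflata array have names ending in X and a number. The meaning of this ending is not stated, and such probes may read more than 1 transcript, so their values are uncertain. These are the probes named here for PETAX002698_Contig2, PETAX006665_Contig3, PETAX002818_Contig2, PETAX002051_Contig2, PETIN001320_Contig2, PETIN069619_Contig1, PETIN029329_Contig5, PETIN005640_Contig1, PETIN011889_Contig1 and PETIN090360_Contig1. The rule for named features was that, where no gene name can be had, at most 2 features that rose and 2 that fell are given per comparison. They were those with the largest fitted difference among called features whose groups do not overlap, an order that for dim or saturated probes is not a measured rank. For tissues, the 2 largest fitted rises with all 3 arrays of the tissue above the other 12 were taken.

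Tissue-raised sets took the place of the gene lists, and were chosen after the files were seen to hold no names. Their members came from the wild species arrays alone and were tested in the seed comparison with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. For the same reason, probes were matched between platforms by identical sequence (1025 probes), with one-to-one probes sharing a run of at least 25 nt (3141) as an alternative. Differences of a tissue effect between species were tested in limma over the identical probes of both platforms in 1 fit, with the same calls as for tissues.

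Groups share replicate numbers in the labels. Same-numbered arrays were checked for common deviations from their group means, by correlation across features. For seeds on the inflata array the 3 pairs correlated at 0.322, 0.110 and 0.122, so the numbers were taken to pair those arrays, from the data and not from a stated batch. For seeds on the axillaris array, and over the 5 tissues compared within a species, not every same-numbered pair did so, and those arrays were not taken as paired. The pairing on the inflata array is uncertain, since R27 replicate 2 correlated higher, at 0.220, with W134 replicate 3. The main fits left the pairing out, as planned, and the replicate number as a block is given as an alternative. Files give no slide or scan number.

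The tests were run on simulated data with the real features' means and spreads, in which 100 features changed 2-fold and 100 changed 4-fold. In the seed comparison 39.0% of 2-fold and 83.0% of 4-fold changes were recovered on the axillaris array (27594 features), and 22.0% and 59.0% on the inflata array (29163 features). In the seedling comparison, counted without the 2-fold minimum of tissue calls, 38.0% and 94.0% were recovered in P. axillaris and 58.0% and 95.0% in P. inflata. False calls made up 2.40% to 6.71% of calls. Fewer features changed than were called in the data, and noise was drawn independently for each feature. These shares thus need not hold for the real arrays.

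The alternatives fixed before the data were examined were no background correction, median scaling, cyclic loess, leaving out dim features at a mild and a stricter limit, medians of spots, the authors' processed values, all 21 arrays of a platform in 1 fit, the replicate number as a block, intensity trend with robust moderation, other thresholds, an ordinary pooled-variance test and leaving out each array in turn. Leaving out X probes, matching over 25 nt, the species differences, the tissue-raised sets and all alternatives run on these were added after seeing the data.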

Results

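Transcript levels were measured in Petunia with custom oligonucleotide arrays, 1 labelled antisense RNA sample per array. The axillaris array carried 27594 Petunia probes from 23260 sequence clusters of Petunia axillaris, and the inflata array carried 29163 probes from 24367 clusters of Petunia integrifolia subsp. inflata, called P. inflata here. Both are wild species. Floral buds, callus, inflorescences, seedlings and fertilized ovaries of each species were measured on the array made from its own sequences, with 3 arrays per tissue. Seeds of R27 and W134, lines of the garden petunia Petunia x hybrida, were measured on both arrays, with 3 arrays per line and platform. A difference between these seeds may lie in transcript level or in each line's match to the wild species probe, which was not tested. The titles give 17 days after pollination for fertilized ovaries and 15, 20 and 25 days for seeds, without saying how these ages fall among the seed samples. R27 is known as a wild-type line and W134 as a line with a mutated AN11, a WD40-repeat regulator of anthocyanin pigments and seed coat development. The 42 arrays formed 14 groups of 3. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. They also do not say whether the same seed RNA was put on both platforms.

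The signal rose only moderately above background. The median Petunia probe was 1.29 to 2.53 times as bright as the median negative-control probe on the P. axillaris tissue arrays and 1.53 to 2.58 times on the P. inflata tissue arrays. On the seed arrays this ratio was 1.36 to 1.75 on the axillaris platform and 1.20 to 1.53 on the inflata platform. The share of Petunia probes brighter than the 95th percentile of the negative controls ran from 29.0% to 54.7% over the tissue arrays and from 30.5% to 44.1% over the seed arrays. Within groups, normalized log2 values correlated between arrays with r from 0.853 to 0.989 across features. The lowest value was between W134 replicates 1 and 3 on the inflata array. The number of arrays limits the precision of every value below.

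The seeds of the mutant and wild-type lines were compared first, with the series' question of pathways impaired in a regulatory mutant in view. Only 1 line of each kind was sampled, so an effect of AN11 cannot be told apart from other differences between the lines or their seeds. No pathway was examined, since no feature has a gene name. On the axillaris array, 2987 of 27594 features differed between W134 and R27 seeds by limma at an adjusted p under 0.05, with 1138 higher and 1849 lower in W134. Of these, 42 were at least 4-fold higher and 145 at least 4-fold lower by fitted difference, which is not measured where the dimmer line was near background. PETAX047481_Contig1 (probe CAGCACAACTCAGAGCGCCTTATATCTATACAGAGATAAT) was at least 23.8-fold higher in W134 (limma adjusted p = 6.52e-05). Its log2 intensity was 13.74 ± 0.15 (SD, n = 3) in W134 seeds, and it was not well above background on any R27 array. PETAX036463_Contig1 (probe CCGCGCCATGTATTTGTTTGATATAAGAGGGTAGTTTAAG) was at least 12.95-fold higher, with 12.86 ± 0.09 (SD, n = 3) in W134 and no R27 array well above background (limma adjusted p = 3.08e-05). Neither of these features was well above background on any of the 15 arrays of P. axillaris tissues. PETAX038429_Contig4 (probe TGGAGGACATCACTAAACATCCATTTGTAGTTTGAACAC) was at least 73.7-fold lower in W134 (limma adjusted p = 0.000111). It was well above background on 1 of 3 W134 arrays and saturated on 2 of 3 R27 arrays, so the size of its difference is not measured beyond this bound. PETAX078379_Contig1 (probe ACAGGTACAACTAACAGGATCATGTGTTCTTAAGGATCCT) was at least 14.1-fold lower in W134, where no array was well above background, against 13.36 ± 0.41 (SD, n = 3) in R27 (limma adjusted p = 0.00012). In P. axillaris the same feature was well above background on all 3 fertilized ovary arrays, at 11.36 ± 0.96 (SD, n = 3), and on none of the other 12. The count of calls leaned on single W134 arrays: it was 1236 without W134 replicate 1, 815 without replicate 2 and 852 without replicate 3.

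On the inflata array, 2572 of 29163 features differed between the lines by limma without the replicate number as a block, with 868 higher and 1704 lower in W134. By fitted difference, 46 were at least 4-fold higher and 308 at least 4-fold lower. Folds of features not well above background in the dimmer line are not measured. Of all features, 25.4% were well above background on all 3 W134 arrays, against 35.9% in R27, so this balance may partly rest on such folds. PETIN003438_Contig1 (probe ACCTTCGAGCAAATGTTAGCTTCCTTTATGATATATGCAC) was at least 13.7-fold higher in W134 seeds, at 12.27 ± 0.34 (SD, n = 3) against no R27 array well above background (limma adjusted p = 0.00165). PETIN024413_Contig1 (probe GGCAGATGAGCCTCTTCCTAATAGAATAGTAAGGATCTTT) was measured in both lines, at 15.18 ± 0.13 in W134 and 10.12 ± 0.20 in R27 (SD, n = 3 each). Its log2 difference was 5.06 (SE 0.15, limma adjusted p = 0.000647). Both features were well above background on all 15 arrays of P. inflata tissues. In the other direction, PETIN077377_Contig1 (probe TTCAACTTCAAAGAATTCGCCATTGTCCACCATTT) was at least 39.1-fold lower in W134, with 14.16 ± 0.37 (SD, n = 3) in R27 and no W134 array well above background (limma adjusted p = 0.000647). It was not well above background on any of the 15 arrays of P. inflata tissues. PETIN013810_Contig1 (probe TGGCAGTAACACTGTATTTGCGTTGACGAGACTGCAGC) was at least 22.5-fold lower, with 13.36 ± 0.02 (SD, n = 3) in R27 (limma adjusted p = 8.28e-05). It was well above background on all 15 P. inflata tissue arrays, yet on no W134 array.

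The counts on the inflata array were less firm than those on the axillaris array. With the replicate number as a block, 652 features were called on the inflata array. Leaving out R27 replicate 1, 2 or 3 gave 343, 283 and 863 calls. Leaving out W134 replicate 2 gave 14 calls, and leaving out W134 replicate 3 gave 6740. Under median scaling 4836 features were called, 84.8% of them lower in W134, against 66.3% lower after quantile normalization. Without W134 replicate 3 the lower share was 47.7%, and without W134 replicate 1 it was 52.8%. The 4 features named for this array kept their direction and stayed past the threshold in each of these fits, which their choice by largest difference made likely.

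**Figure D1:**
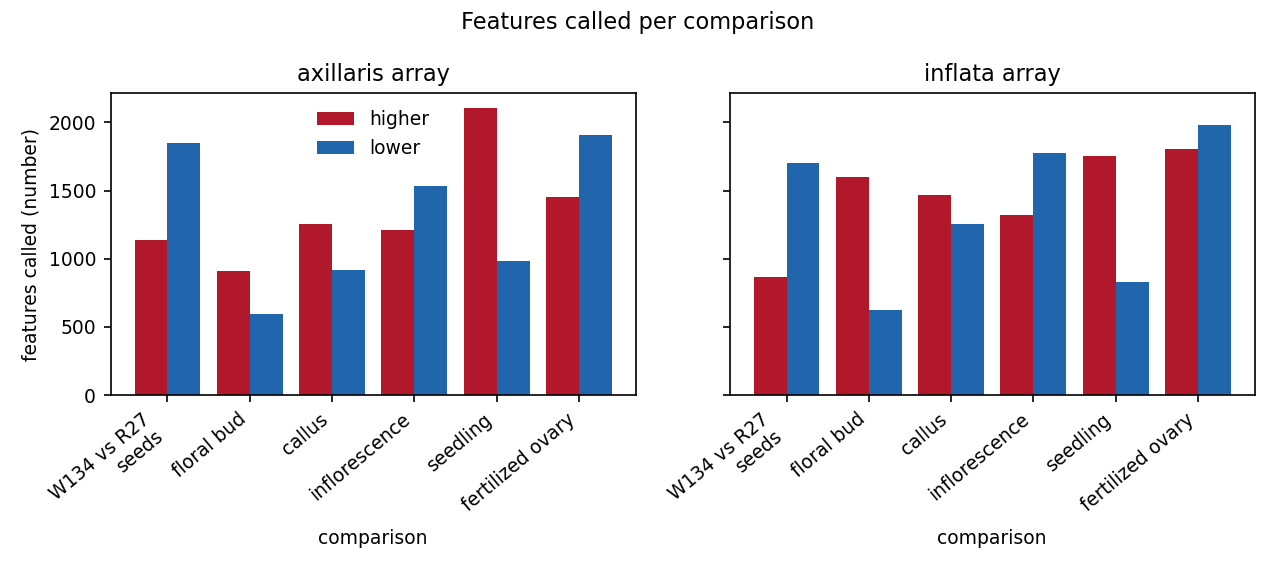
Number of features called (vertical axis) in each comparison (horizontal axis) on the axillaris array (left) and the inflata array (right), split into higher (red) and lower (blue) features. Lower features outnumber higher ones in W134 seeds on both arrays (1849 against 1138 and 1704 against 868), and seedlings show the opposite balance (984 against 2106 and 828 against 1754).

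The line differences on both platforms resembled each other. If the same seed RNA was put on both, which the labels do not say, this would partly come from shared samples. Identical probes would also share any difference in how the lines match them. Over the 1025 probes whose sequence is identical on the arrays, the log2 differences between W134 and R27 correlated with a Pearson r of 0.873 and a Spearman rho of 0.822 across probes, which are not independent replicates. The sign was the same for 80.7% of them. On both arrays 83 probes were called lower in W134, where independent lists would share 19.4, and 19 were called higher, where independent lists would share 1.15. These counts rest on the inflata fit without the replicate number as a block, whose 2572 calls fell to 652 with it. No probe was called in opposite directions, where independent lists would give 9.44. Without W134 replicate 3 on the inflata array, r was 0.782.

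**Figure D2:**
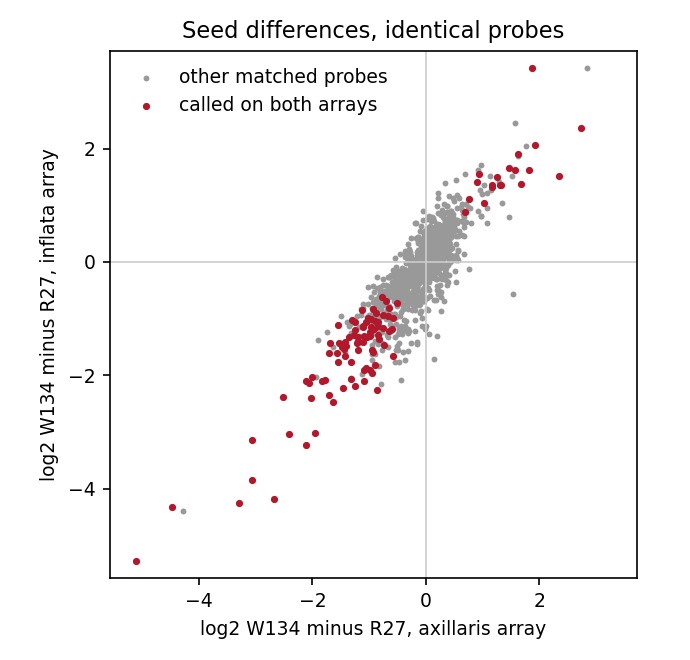
Log2 difference between W134 and R27 seeds on the axillaris array (horizontal axis) and the inflata array (vertical axis) for the 1025 probes of identical sequence. Each point is a probe, and red points were called on both arrays. The red points are 19 higher and 83 lower in W134, with none in opposite quadrants.

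Features that mark single tissues of the wild species were then followed into the seeds. For each tissue a set was formed, after the files were seen to hold no gene names, of features raised at least 2-fold over the other 4 tissues and brighter on its 3 arrays than on the other 12. The sets held 377 features for floral bud, 627 for callus, 723 for inflorescence, 1166 for seedling and 937 for fertilized ovary in P. axillaris. In P. inflata they held 699, 781, 855, 889 and 1280. Among features raised in inflorescences, more were lower than higher in W134 seeds on both arrays, and most did not pass limma's threshold. On the axillaris array 151 of the 723 were lower, 19 were higher and 553 did not pass. Their mean fitted log2 difference minus that of other features, called the shift here, was -0.29. Camera in limma compares t-statistics of the set and the other features, and not this shift itself. It gave adjusted p = 1.16e-08 with the preset correlation, and adjusted p = 0.0994 with an estimated correlation, where the call was lost. With the adjustment made over the set alone, 212 were lower and 33 higher. On the inflata array 131 of the 855 were lower, 18 were higher and 706 did not pass. Their shift was -0.36. Camera in limma gave adjusted p = 9.15e-07 with the preset correlation, and adjusted p = 0.419 with an estimated correlation, where the call was lost. With the adjustment over the set alone, 187 were lower and 30 higher. The rotation test in limma, fry, which asks whether the set itself changed and compares it with no other features, gave adjusted p = 0.00597 and adjusted p = 0.0307. Signal over background was lower in W134 as well: over all features, 32.7% in R27 and 29.4% in W134 were well above background on all 3 axillaris arrays, against 49.0% and 37.5% in the set. These shares were 35.9% and 25.4%, against 44.8% and 26.5% in the set, on the inflata array. The set's mean level was lower on every W134 array than on every R27 array of the same platform, which chance gives in 10% of splits, counting both directions. The seedling set (lower in W134) and the floral bud set (higher in W134), which did not pass camera's threshold, were separated as fully on the axillaris array.

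The other 4 sets did not pass camera's threshold on either array. The shift of the floral bud set was 0.08 on the axillaris array (camera in limma, adjusted p = 0.0557) and 0.03 on the inflata array (adjusted p = 0.311). For callus it was 0.11 (camera in limma, adjusted p = 0.0557) and 0.07 (adjusted p = 0.311). The callus set passed on the axillaris array without R27 replicate 2 (0.16) and without W134 replicate 1 (0.14), while over all 6 arrays an estimated correlation gave a limma adjusted p = 0.498. For seedling it was -0.05 (camera in limma, adjusted p = 0.629) and -0.03 (adjusted p = 0.886). The seedling sets had a mean below 0 and a median above 0 on both arrays, and camera's direction was down on the axillaris array and up on the inflata array. For fertilized ovary the shift was 0.09 (camera in limma, adjusted p = 0.629) and -0.11 (adjusted p = 0.162), and it passed on the inflata array without R27 replicate 3 (-0.16), while over all 6 arrays an estimated correlation gave a limma adjusted p = 0.645. On the axillaris array the ovary shift rested on W134 replicate 1, without which it was -0.00521. Called members of the fertilized ovary sets were 79 lower and 43 higher in W134 on the axillaris array, and 125 lower and 33 higher on the inflata array. For the seedling sets these counts were 92 lower and 41 higher, and 70 lower and 36 higher. Over all called features 61.9% were lower in W134 on the axillaris array and 66.3% on the inflata array, so lower features predominated in general.

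**Figure D3:**
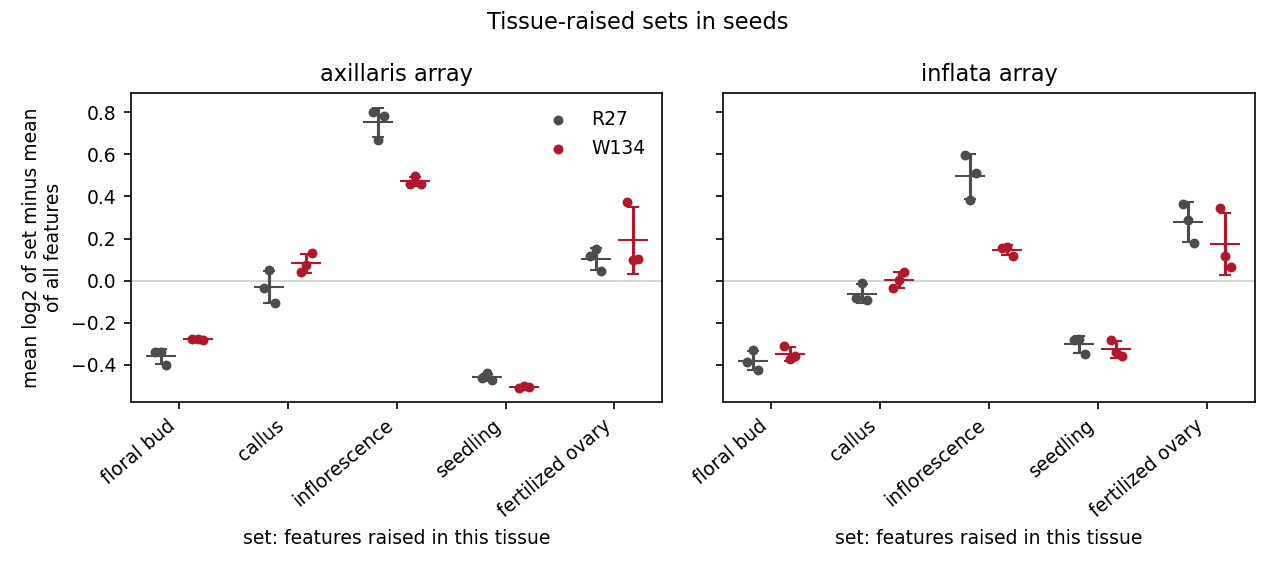
Mean log2 intensity of each tissue-raised set minus the mean of all features (vertical axis) on every R27 (grey) and W134 (red) seed array, for the sets on the horizontal axis, with the axillaris array at left and the inflata array at right. Points are single arrays, and bars show the mean and SD of 3 arrays. The inflorescence set lies at 0.67 to 0.80 in R27 and 0.46 to 0.50 in W134 on the axillaris array, and at 0.38 to 0.59 and 0.12 to 0.16 on the inflata array.

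Each tissue of the wild species was compared with the mean of the other 4, which describes where in the plant the catalogued transcripts were found. In floral buds of P. axillaris 911 features were higher and 598 lower by limma at an adjusted p under 0.05 and at least 2-fold. PETAX002279_Contig2 was at least 134.3-fold higher in buds, at 15.80 ± 0.05 (SD, n = 3), saturated on all 3 arrays and not well above background on any of the other 12 (limma adjusted p = 1.09e-13). PETAX002698_Contig2 was at least 116-fold higher (limma adjusted p = 3.93e-13). In floral buds of P. inflata 1597 features were higher and 627 lower. PETIN001320_Contig2 was at least 102-fold higher and PETIN002802_Contig1 at least 120-fold higher there, and neither was well above background on any of the other 12 arrays (limma adjusted p = 4.33e-12 and 1.05e-10).

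In callus, undifferentiated tissue in culture, 1255 features were higher and 919 lower in P. axillaris by limma, and 1468 were higher and 1251 lower in P. inflata. PETAX000042_Contig1 was at least 99.4-fold higher in P. axillaris callus (limma adjusted p = 1.14e-12), and 3 of the other 12 arrays were above background. A probe of P. inflata that shares at least 25 nt with it was at least 62.5-fold higher in callus of that species (limma adjusted p = 1.48e-09). PETAX006665_Contig3 was at least 57.9-fold higher in P. axillaris callus (limma adjusted p = 1.69e-10). In P. inflata callus PETIN069619_Contig1 was at least 77.4-fold higher and PETIN029329_Contig5 at least 38.1-fold higher, each above background on 2 of the other 12 arrays (limma adjusted p = 5.43e-08 and 2.64e-08).

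In inflorescences 1209 features were higher and 1530 lower in P. axillaris by limma, and 1318 were higher and 1773 lower in P. inflata. PETAX002818_Contig2 was at least 49.8-fold higher (limma adjusted p = 1.99e-10) and PETAX023196_Contig1 at least 34.3-fold higher (limma adjusted p = 4.11e-08), each above background on 4 of the other 12 arrays. The identical probe on the inflata array to that of PETAX023196_Contig1 was at least 18.1-fold higher in P. inflata inflorescences (limma adjusted p = 5.83e-09). In P. inflata the features named are contigs of 1 cluster. PETIN005640_Contig1 was at least 12.1-fold higher and PETIN005640_Contig2 at least 13.01-fold higher (limma adjusted p = 2.54e-08 and 1.72e-07).

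Seedlings had the highest number of raised features among the P. axillaris tissues, with 2106 higher and 984 lower by limma. In P. inflata seedlings 1754 were higher and 828 lower. PETAX041920_Contig1 was at least 26.8-fold higher, at 14.07 ± 0.04 (SD, n = 3, limma adjusted p = 1.65e-05), and PETAX006178_Contig1 at least 22.0-fold higher (limma adjusted p = 4.31e-09) in P. axillaris. In P. inflata PETIN015975_Contig1 was at least 42.7-fold higher, at 14.51 ± 0.36 (SD, n = 3, limma adjusted p = 5.72e-09), and PETIN011889_Contig1 at least 36.0-fold higher (limma adjusted p = 3.39e-09). The identical probe on the axillaris array to that of PETIN015975_Contig1 was at least 14.5-fold higher in P. axillaris seedlings (limma adjusted p = 1.71e-07). Between 3 and 4 of the other 12 arrays were above background for the 4 features named first, and 5 of 12 for this identical probe.

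Fertilized ovaries differed from the other tissues in the most features in both species, with 1455 higher and 1905 lower in P. axillaris and 1805 higher and 1979 lower in P. inflata by limma. In P. axillaris the features named are contigs of 1 cluster, with PETAX002051_Contig3 at least 94.7-fold higher and PETAX002051_Contig2 at least 139-fold higher, neither well above background on any of the other 12 arrays (limma adjusted p = 2.12e-12 and 1.31e-12). A P. inflata probe that shares at least 25 nt with that of PETAX002051_Contig2 was at least 66.7-fold higher in ovaries of that species (limma adjusted p = 2.33e-13). In P. inflata PETIN007268_Contig2 was at least 96.7-fold higher (limma adjusted p = 2.43e-13) and PETIN090360_Contig1 at least 67.1-fold higher (limma adjusted p = 2.33e-13). For these, 2 and 3 of the other 12 arrays were above background.

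The tissue differences of the species resembled each other over the 1025 identical probes. The Pearson r across probes was 0.813 for inflorescence, 0.768 for seedling, 0.767 for fertilized ovary, 0.697 for callus and 0.538 for floral bud. The Spearman rho was 0.759, 0.662, 0.671, 0.616 and 0.508. Different tissues of the species correlated between -0.441 and 0.274, so each tissue was most like the same tissue of the other species. Raised in both species were 44 probes in floral bud, 38 in callus, 47 in inflorescence, 81 in seedling and 53 in fertilized ovary, where independent lists would share 5.27, 4.38, 5.26, 14.4 and 8.51. Opposite calls numbered 6 in floral bud, 3 in callus, 4 in fertilized ovary and 0 in inflorescence and seedling. Independent lists would give 6.30, 10.5, 23.8, 15.0 and 12.2.

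**Figure D4:**
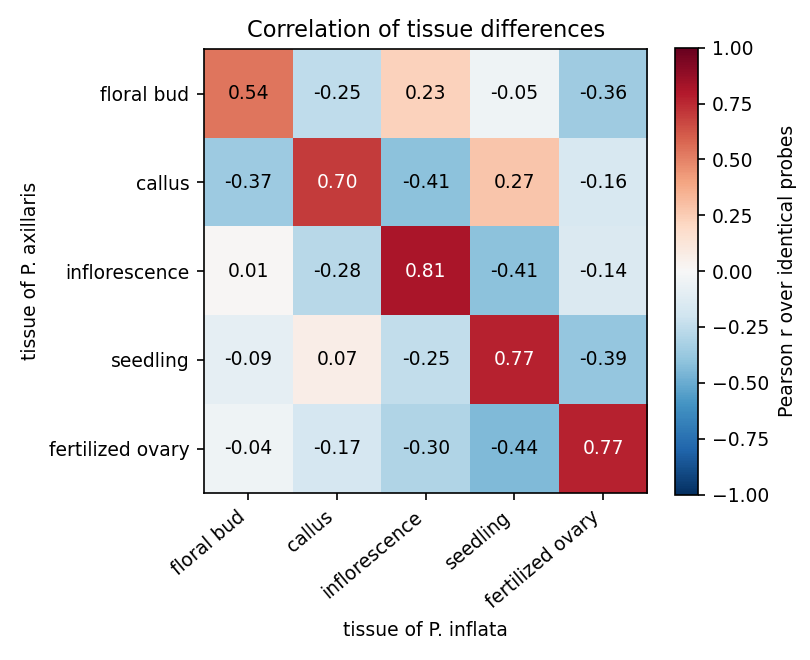
Pearson correlation of the log2 differences of each P. axillaris tissue (vertical axis) with those of each P. inflata tissue (horizontal axis) over 1025 identical probes, with colour from blue (-1) to red (1). The diagonal runs from 0.54 for floral bud to 0.81 for inflorescence, and every other cell lies between -0.44 and 0.27.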

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

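The tests of scaling, of single arrays (for the seed balance and for floral bud) and of the brightness of the inflorescence set were chosen only after the result was seen. The tissue effect itself differed between the species for some of the 1025 identical probes, by an interaction test in limma. These were 95 probes in fertilized ovary (44 with the higher effect in P. inflata and 51 in P. axillaris), 69 in floral bud (50 and 19), 68 in callus (26 and 42), 52 in seedling (30 and 22) and 26 in inflorescence (10 and 16). In 100 regroupings that moved arrays between the species within each tissue, the real one included, 1 gave as many calls for each tissue, the real one. The highest other counts were 41, 38, 57, 15 and 9. At this number of regroupings, this argues against chance for a species difference in any tissue at all. Arrays of all tissues were moved at once, so no tissue is tested by itself. Species and platform cannot be separated in this test, since each species was measured on its own array only.

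Floral bud differences were less alike between the species than those of the other tissues, with r of 0.538 against 0.697 to 0.813. They also had the smallest spread over probes, with an SD of 0.739 in P. axillaris and 0.797 in P. inflata. For fertilized ovary the SD was the largest, at 1.10 and 1.06. Noise in smaller differences is argued against: corrected for the reliability of the fitted differences, r was 0.5998 for floral bud and at least 0.765 for the others. A single mislabelled or mixed array is argued against as well, since r for floral bud reached no more than 0.546 with any 1 array left out, and that of no other tissue fell below 0.660. What stays open, untested, is that the buds of the species may have differed in stage, which the labels do not give. The smaller spread of bud differences can also lower r and was not tested. The interaction test called 95 probes in fertilized ovary, 69 in floral bud and 68 in callus, so buds did not have the most calls. Counts of calls do not measure how large the differences were, so whether the species differed most in buds is not settled.

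Control probes outside the comparisons gave signals above the negative controls. Probes with names starting in D had a median brightness, over the arrays, of 2.03 times the negative controls on the axillaris array and 1.95 times on the inflata array. For control probes with names starting in NM the ratio was 1.18 and 1.45. All 4 ratios were above 1 on each of the 21 arrays of a platform.

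Among called features, more were lower than higher in W134 seeds on both arrays, although over all features only 43.8% and 43.9% had a lower mean in W134. Scaling of the arrays is argued against as the whole cause, because over median scaling, cyclic loess and no background correction the lower share of called features was at least 58.9%. Weaker signal over the negative controls on the W134 arrays was examined in the brightest features (upper 25% by mean over the 6 arrays). Their lower share was 57.9% on the axillaris array (exact 95% interval 55.4% to 60.5%, over features, which are not independent) and 61.9% on the inflata array. This argues against weaker signal as the whole cause only as far as these features lay above background in both lines, which was not checked. Features bright in R27 and near background in W134 can enter by their mean. Weaker signal may add to the balance, since in the other features the share was higher, at 65.7% and 69.3%. On the axillaris array the lower share was at least 59.5% with any 1 array left out, but on the inflata array it fell to 47.7% without W134 replicate 3, so the balance there may rest on that array, while a difference between the lines stays open, as a hypothesis, on both arrays.

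Inflorescence-raised features had a lower mean in W134 seeds, which was weighed against brightness and mixed tissue. Brightness of the set is argued against, since 0 of 1000 random sets matched on mean intensity had a mean difference as low on either array. Inflorescence tissue mixed into the R27 samples cannot be told apart from a line difference: among members abundant in inflorescence and dim in seeds, 65.5% had a lower mean in W134 on the axillaris array and 75 of 125 on the inflata array, but on W134 arrays 0 of these were above background on all 3, so noise can set their sign. A difference between the lines or in the stage of their seeds could also account for the lower mean and was not tested for this set. Signal over background was weaker on W134 arrays, with 25.4% of all features above it on all 3 inflata arrays, against 35.9% in R27. This was tested for the set only in part, by leaving out dimmer features. At the preset correlation the set stayed past camera's threshold there, as in 16 of the 17 alternatives on each array. All of those 16 kept the preset correlation, so they do not vary the assumption on which the call depends. Only given that correlation does this argue against dim members as the whole cause. Features kept there can still lie near background on W134 arrays, so weaker signal may add to the lower mean. Members vary together, and with an estimated correlation the lower mean is not past the threshold on either array.

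For the seed comparison the 6 arrays of a platform make 10 splits, too few for a share under 0.05. On the axillaris array the real split gave 2987 calls and the highest other 0, with 1 split as high. On the inflata array these were 2572 and 1, with 1 split as high. There the real split parts all 3 pairs of same-numbered arrays, and the 3 other splits that do so gave 0 calls. The largest shift of a tissue-raised set was 0.287 in size on the axillaris array against 0.169 in the highest other split, and 0.362 against 0.222 on the inflata array. For the tissues, 1 of 100 regroupings of the 15 arrays, the real one, gave as many calls for each of the 10 comparisons. The highest other counts in P. axillaris were 217 for floral bud, 1076 for callus, 1839 for inflorescence, 925 for seedling and 1683 for fertilized ovary. In P. inflata they were 682, 2273, 164, 543 and 1211. The regroupings shuffled all 15 arrays at once and did not keep same-numbered arrays together. At this number, they argue against chance only for tissues differing at all. Real differences of other tissues enter the spread of each regrouping, so no single comparison is tested by itself.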

How the results depend on the processing

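The tests of X probes, of matching over 25 nt, of the tissue-raised sets, of the species differences and, for agreement between arrays, of loess, background, spot medians and the stricter limit on dim features were chosen only after the result was seen. Weak signal over background limits all counts. All 649 values of the 28 named features under alternatives kept direction and side of the threshold. Their choice by largest difference in these same arrays made this likely, and it does not extend to other calls. Of the other values under alternatives without a left-out array, 291 stayed within 1.5 times (counts), within their spread (correlations) or on their side of the threshold (sets), 60 moved further, 2 lost a call, 12 gained one and 0 reversed. The planned tests on gene lists were not run, since no feature has a gene name. The causes of the changes below were not tested, except that thresholds, feature numbers and array numbers act by construction. Seed calls (main 2987 axillaris, 2572 inflata) were 1198 and 1857 at 2-fold or more, 620 and 173 with the pooled-variance test, 1417 and 4913 with 21 arrays in 1 fit, and 4836 with median scaling (inflata). Under cyclic loess 71.2% and 63.5% of calls were lower, and under median scaling 68.4% and 84.8%, against 61.9% and 66.3%; the median difference of all features was then 0.21 and 0.12, against 0.04 and 0.05. With the replicate number as a block they were 1425 and 652, and the block moved no other count by over 1.5 times and changed no call of a set; on the axillaris array the same-numbered arrays correlated at -0.0531 to 0.0603, and among tissues 17 of 30 same-numbered pairs (P. axillaris) and 13 of 30 (P. inflata) were over 0.1; all 3 were for P. axillaris callus with inflorescence (0.272 to 0.486), callus with ovary (0.136 to 0.475) and inflorescence with ovary (0.478 to 0.544), and P. inflata floral bud with inflorescence (0.406 to 0.594). With 1 array left out, seed calls ran from 815 to 3570 and from 14 to 6740, and their correlation between arrays from 0.782 to 0.877. The authors' realigned values gave 2907 and 2069 seed calls. Of these, 2334 and 1454 were also among the 2987 and 2572 called here, all in the same direction, which the use of the same arrays made likely. Seed columns of the authors' values held empty cells, up to 7726 (W134 replicate 1, inflata array).

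Tissue calls, in the order floral bud, callus, inflorescence, seedling, ovary, were 759, 1058, 1188, 1490 and 1748 without background correction in P. axillaris and 1054, 1336, 1420, 1261 and 1774 in P. inflata. With the authors' values they were 755, 1078, 1220, 1500 and 1740, and 1065, 1356, 1458, 1283 and 1802. With no minimum fold they were 2299, 3391, 5102, 5072 and 5361, and 4419, 5235, 6345, 4969 and 7727. Without the dimmest 50%, P. axillaris callus had 1424, and floral bud r was 0.602.

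Species differences, in the same order, were 44, 42, 17, 23 and 51 without background correction, 45, 40, 16, 23 and 51 with the authors' values, 38, 41, 14, 27 and 59 without the dimmest 50%, and 196, 208, 71, 153 and 266 over probes sharing 25 nt, where more probes were tested.

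The inflorescence set's shifts of -0.29 and -0.36 lost their call with the estimated correlation (limma adjusted p = 0.0994 and 0.419). They were past the threshold in 16 of the 17 alternatives run with camera on each array (range over these 17, 1.08e-10 to 0.0994 and 1.11e-08 to 0.419). Those 16 all kept the preset correlation. Among them, the upper 50% of intensity and leaving out the dimmest 50% kept the same features. On the axillaris array the callus set gained a call at 0.12 (loess), 0.20 (upper 50% of intensity, or without the dimmest 50%), 0.11 (authors' values) and 0.15 (without the dimmest 25%), and with 1 array left out it ran from 0.0764 to 0.156, passing without R27 replicate 2 (0.16) or W134 replicate 1 (0.14); with an estimated correlation limma gave adjusted p = 0.498. The floral bud set did so at 0.0899 (loess), 0.16 (upper 50%, or without the dimmest 50%), 0.12 (median scaling) and 0.11 (without the dimmest 25%), and on the inflata array at 0.12 (median scaling); with an estimated correlation limma gave adjusted p = 0.0994 and 0.645. By fry, which compares the set with no other features, the axillaris floral bud set passed with its own mean of 0.0821 (limma adjusted p = 0.00597; over its 17 alternatives with camera, 0.0118 to 0.246). The inflata ovary set ran from -0.200 to -0.0514 with 1 array left out, passing without R27 replicate 3 (-0.16); with an estimated correlation limma gave adjusted p = 0.645.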

Other observations

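Tissues of a species grouped alike on both platforms. Floral bud and inflorescence correlated at r of 0.912 across features in P. axillaris and 0.888 in P. inflata, and callus and seedling at 0.890 and 0.907. Seedling and fertilized ovary were the least alike among the tissue pairs, at 0.778 and 0.805. Mean profiles of R27 and W134 seeds correlated at 0.954 on the axillaris array and 0.919 on the inflata array. R27 seeds stood closest to fertilized ovaries among the wild tissues on both arrays, at 0.783 and 0.721, and W134 seeds likewise at 0.783 and 0.706. For R27 this was a near tie, with inflorescence at 0.781 and 0.717. Species and normalization differ between these seeds and tissues, so the levels are descriptive.

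Of the features lower in W134 seeds, 11.6% were raised in inflorescence on the axillaris array and 11.2% on the inflata array, against 4.38% and 4.52% of all features. Of the features higher in W134, 3.51% and 3.34% were so. Features raised in fertilized ovary made up 8.27% and 10.4% of the lower ones and 6.41% and 5.30% of the higher ones, against 5.27% and 6.19% of all features. For seedling the shares were 9.63% and 8.74% of the lower ones and 7.47% and 9.10% of the higher ones, against 7.63% and 6.01%. For floral bud they were 3.35% and 7.63% of the lower ones and 6.59% and 7.83% of the higher ones, against 3.30% and 5.48%. For callus they were 6.003% and 6.57% of the lower ones and 7.21% and 8.18% of the higher ones, against 4.55% and 5.03%. These shares count tissue calls without the requirement that arrays do not overlap, and no test was run on them beyond the set tests.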
